A study of Mus musculus with 10 samples.

How the data were processed

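Whole back skin of C57BL/6J mice was profiled on 10 arrays, 1 per sample. In 8 samples a silicone expander lay under the skin. In the 4 expanded samples it had been enlarged with injections of PBS (phosphate-buffered saline), and in the 4 non-expanded samples it had been implanted and left unfilled. Each of these arms had 1 array at days 0, 7, 14 and 21 after full injection. The sample titles number the time points 1 to 4, and these were read in order as the 4 days. The remaining samples were skin without surgery, 1 in telogen (the resting stage of the hair cycle) and 1 in anagen (the growth stage). Per the labels' protocols, total RNA came from whole skin with a Qiagen RNeasy kit and was labelled with biotin by the Affymetrix WT PLUS method. The submitters' processing notes name mm10 as the genome build.

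The deposited values were read as log2 probe-set signals, 1 value for each of 28846 probe sets on each array, with array medians from 6.27 to 6.45. Per the labels, neither the log base nor the background correction, summarisation or normalization is stated, so the base was taken from the platform and from the range of the values, 1.88 to 19.88. On at least 1 array, 586 probe sets lay above 16, the log2 limit of a 16-bit scanner, so the log2 differences are on the deposited scale, which may be stretched. The median of the 23 background probe sets was 5.46, and 1486 of the 13653 genes tested (10.9%) had a mean level below it. The precision is limited by the number of arrays.

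A gene symbol was given for 19572 probe sets, 1 symbol each, and all 19572 were found by gene identifier in the RefSeq table of the mm10 assembly, from which gene positions were taken. Another 9243 probe sets had no symbol and 31 were platform controls, and these were left out of the comparisons. The symbols named 19505 genes. For the 55 genes with several probe sets, the probe set with the highest mean was used. Genes whose mean level lay under the 30th percentile (4.86) were removed, which left 13653.

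Differences were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. All tests were two-sided. The expansion effect compared the 4 expanded with the 4 non-expanded arrays, with the day as a block, which left 3 residual degrees of freedom. Straight lines over the days were fitted within each arm and compared between arms, with 4 residual degrees of freedom, and their slopes are given as the change over 21 days. The implantation effect compared non-expanded skin with the telogen and anagen arrays together, in a fit of all 10 arrays with 7 residual degrees of freedom. The comparison of anagen with telogen, and of both arms on single days, had 1 array a side, so no p-value was computed. With 4 pairs, an exact permutation test could not go below 0.125. Nothing in the labels says whether an array held 1 animal or a pool. The p-values of single genes therefore measure only the spread between these arrays. The arrays of an arm lie at different days and are not plain replicates. Camera with a preset correlation, described below, sets a list against all other genes, so its p-values do not measure replication between arrays.

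The labels number the time points alike in both arms, so the numbers pair the arrays by day, and the day entered the main fit for that reason. Deviations of same-day arrays from their arm means correlated across genes at -0.133, -0.171, -0.104 and 0.358 for days 0, 7, 14 and 21. The pairing thus rests on the labels, not on these values.

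Before the data were examined, 36 lists of marker and pathway genes were fixed. The lists of B and plasma cells (0 genes tested) and of red blood cells (1 gene tested) could not be used. A rule fixed at the same time added the 150 genes highest in anagen over telogen and the 150 genes highest in telogen over anagen; these were chosen on 2 of the 10 arrays and not on the arrays of the expansion effect. Lists were tested against all other genes with camera in limma, with a preset correlation of 0.01 between genes and, beside it, with a correlation estimated from the data. Camera for the slopes within each arm was added after seeing the data. Where there were 1 array a side, the median of a list was placed among 10000 random lists of the same size matched on mean level.

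Genes are named by a rule fixed at the same time. It takes the 12 largest rises and falls that pass the threshold in each comparison, filled up from genes with unadjusted p under 0.01 that do not pass. In the expansion effect the sign had to be the same at all 4 days. Up to 4 members with the smallest p are named for a list, and Lgr6, Lgr5, Krt14, Krt10, Krt16, Mki67, Yap1, Ccn1, Ccn2, Col1a1 and Col3a1 are reported in the expansion effect whatever their values. Krt6a was also in the rule but was not among the named probe sets. Predicted genes and small RNA genes were not named.

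The code was tested on simulated data for 13653 genes, of which 200 were changed by known amounts, in 10 runs. In the expansion effect, 0.05%, 68.4% and 97% of the genes changed by 1, 2 and 4 on the log2 scale were recovered. In the implantation effect the shares were 0%, 41.8% and 91.8%. For a change of 4 over 21 days, 76.2% were recovered within the expanded arm, 74.2% within the non-expanded arm and 1.85% in the difference between arms. Camera with the preset correlation found a shifted list of 20 genes in 10 of 10 runs in each comparison. An unshifted list had an unadjusted p under 0.05 in 1 of 10 runs for the difference in time trend and for the non-expanded trend. In the other comparisons it had 0. The simulated genes were drawn independently, so these runs cannot show how often camera falsely calls a list of co-regulated genes.

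Each comparison was repeated with no filter, a filter at the 50th percentile, quantile normalization, centring of each array, a trended and robust prior, and the mean of all probe sets of a gene. It was also repeated without each day in turn and without the block by day, or with it for the trend, and the implantation effect with the telogen or anagen array alone. The mean of the skeletal muscle, hair or immediate early list was added as a covariate after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.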

Results

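Gene expression in whole back skin was measured on 10 arrays: 4 of expanded skin and 4 of non-expanded skin, with 1 array of each at days 0, 7, 14 and 21 after full injection of the expander, and 1 each of telogen and anagen skin without surgery. Values are log2 signals on the deposited scale, and the depth of an array is not a count. Array medians lay between 6.27 and 6.45. The series title concerns mechanical tension and epidermal stem cells marked by Lgr6, a receptor for R-spondins, in the growth of skin. The arrays that correlated least were telogen and anagen (Pearson r = 0.891 across all probe sets, which are not independent replicates). Those that correlated most were expanded skin at days 0 and 14 (r = 0.98).

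The expansion effect asks how stretched skin differed from skin over an unfilled expander. Single genes of developing muscle, such as Myh3, stood far higher in expanded skin, and genes of adult muscle fibres stood lower. Myh3, the embryonic myosin heavy chain (chromosome 11, 67078273 to 67102291, mm10), averaged 13.16 ± 1.28 in expanded and 5.91 ± 1.24 in non-expanded skin (SD, n = 4 arrays each). Its log2 difference was 7.24 ± 0.86 (SE), with expanded skin higher at all 4 days. The troponins Tnnt2 and Tnni1, used by the heart and by slow muscle, differed by 4.41 ± 0.58 and 4.66 ± 0.98, Mymk, needed for the fusion of muscle precursors, by 2.62 ± 0.79, and Ncam1, a cell adhesion molecule, by 3.17 ± 0.66. Mstn, which encodes the muscle growth inhibitor myostatin (chromosome 1, 53061640 to 53068079), averaged 5.74 ± 1.30 in expanded and 10.92 ± 1.78 in non-expanded skin, a difference of -5.17 ± 0.58. The skeletal muscle genes Tnnc2, Tnni2, Tcap and Eno3 differed by -2.46 ± 0.37, -2.61 ± 0.63, -2.58 ± 0.57 and -2.75 ± 0.57. Apobec2, Ppp1r3a and Tmod4, also of muscle, differed by -3.58 ± 0.63, -3.47 ± 0.76 and -2.64 ± 0.55. Some of these signals lay near background, which limits the size of the differences. Against a background median of 5.46, Tnni1 and Mymk averaged 4.93 and 5.39 in non-expanded skin, where Myh3 read 5.09, 5.15 and 5.69 at days 7, 14 and 21, and Mstn read 5.40 and 4.25 in expanded skin at days 0 and 7. As a group, skeletal muscle genes fell: 20 of 22 were lower, with a median of -1.50 (camera adjusted p = 3.24e-11, and adjusted p = 0.58 with an estimated correlation), and 9 were lower when adjusted over the list alone. The median of the skeletal muscle list was 0.01 at day 0, with 11 of 22 higher, and -2.86, -2.57 and -0.73 at days 7, 14 and 21. Muscle regeneration genes rose, with 4 of 5 higher and a median of 0.95 (adjusted p = 0.0033, and adjusted p = 0.58 with an estimated correlation), and 2 passed when adjusted over the list alone. Of the 9 genes of this list, all on the array, only these 5 passed the level filter. With the mean of the skeletal muscle list as a covariate, a fit chosen after seeing the data, the muscle regeneration call ended (adjusted p = 0.143). No single gene of either group passed over all genes tested.

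**Figure D1:**
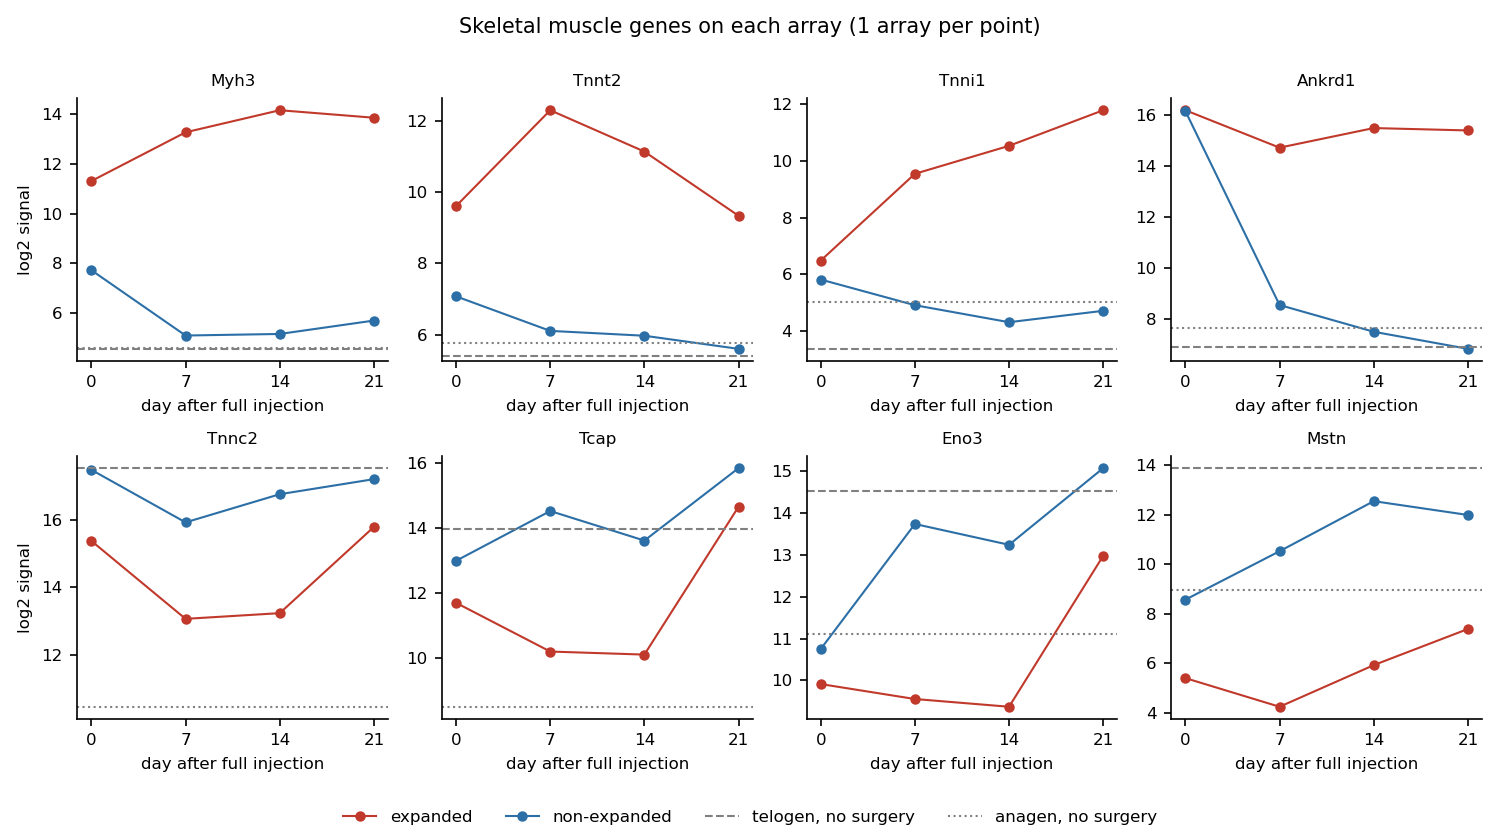
Log2 signal of 8 muscle genes (y axis) against the day after full injection, 1 array per point, with the telogen and anagen arrays as horizontal lines. Myh3 was higher in expanded skin at all 4 days and Mstn lower at all 4 days.

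Target genes of YAP and TAZ and immediate early genes were higher in expanded skin, while the adhesion and mechanosensing list was not called (9 of 17 higher, adjusted p = 0.32). Ccn2, a matrix protein and target of the mechanosensitive factors YAP and TAZ (chromosome 10, 24595442 to 24598683), averaged 13.72 ± 1.09 against 10.88 ± 0.49 (SD, n = 4 each), a difference of 2.84 ± 0.49. Ankrd1, a YAP/TAZ target that striated muscle also expresses, differed by 5.66 ± 1.33, Ccn1 by 1.56 ± 0.51, Fjx1 by 0.96 ± 0.22 and the matrix protein gene Thbs1 by 3.00 ± 0.34. At day 0 Ankrd1 read alike in both arms (16.17 expanded, 16.13 non-expanded), so its difference lay at days 7, 14 and 21. YAP/TAZ target genes rose as a group, with 18 of 21 higher and a median of 0.74 (adjusted p = 2.53e-05, and adjusted p = 0.58 with an estimated correlation), and 3 passed over the list alone. At day 7 the YAP/TAZ target genes were not higher, with 9 of 21 higher and a median of -0.32 (percentile 6.84), against medians of 0.97, 0.36 and 0.82 at days 0, 14 and 21. Yap1 itself differed by -0.04 ± 0.36. The immediate early genes, switched on within minutes by many stimuli, rose beside them: 15 of 15 were higher, with a median of 1.42 (adjusted p = 1.82e-09, and adjusted p = 0.58 with an estimated correlation), and 4 passed over the list alone. Among them, Fosb, Fos, Ier3 and Zfp36 differed by 3.04 ± 0.66, 3.05 ± 0.90, 1.74 ± 0.34 and 1.72 ± 0.48. With the mean of the immediate early genes as a covariate, a fit chosen after seeing the data, the call of the YAP/TAZ target genes ended (adjusted p = 0.213, 11 of 21 higher). Hippo pathway components, a list of upstream kinases and cofactors that also holds Yap1, Wwtr1 and the Tead genes, rose slightly. Of these, 15 of 19 were higher, with a median of 0.26 (adjusted p = 0.0322, and adjusted p = 0.685 with an estimated correlation). Mob1a and Wwtr1, which encodes TAZ, differed by 0.68 ± 0.23 and 0.68 ± 0.28, and the Hippo call ended without day 0 (adjusted p = 0.204), without day 21 (adjusted p = 0.158) or with the immediate early covariate (adjusted p = 0.809).

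**Figure D2:**
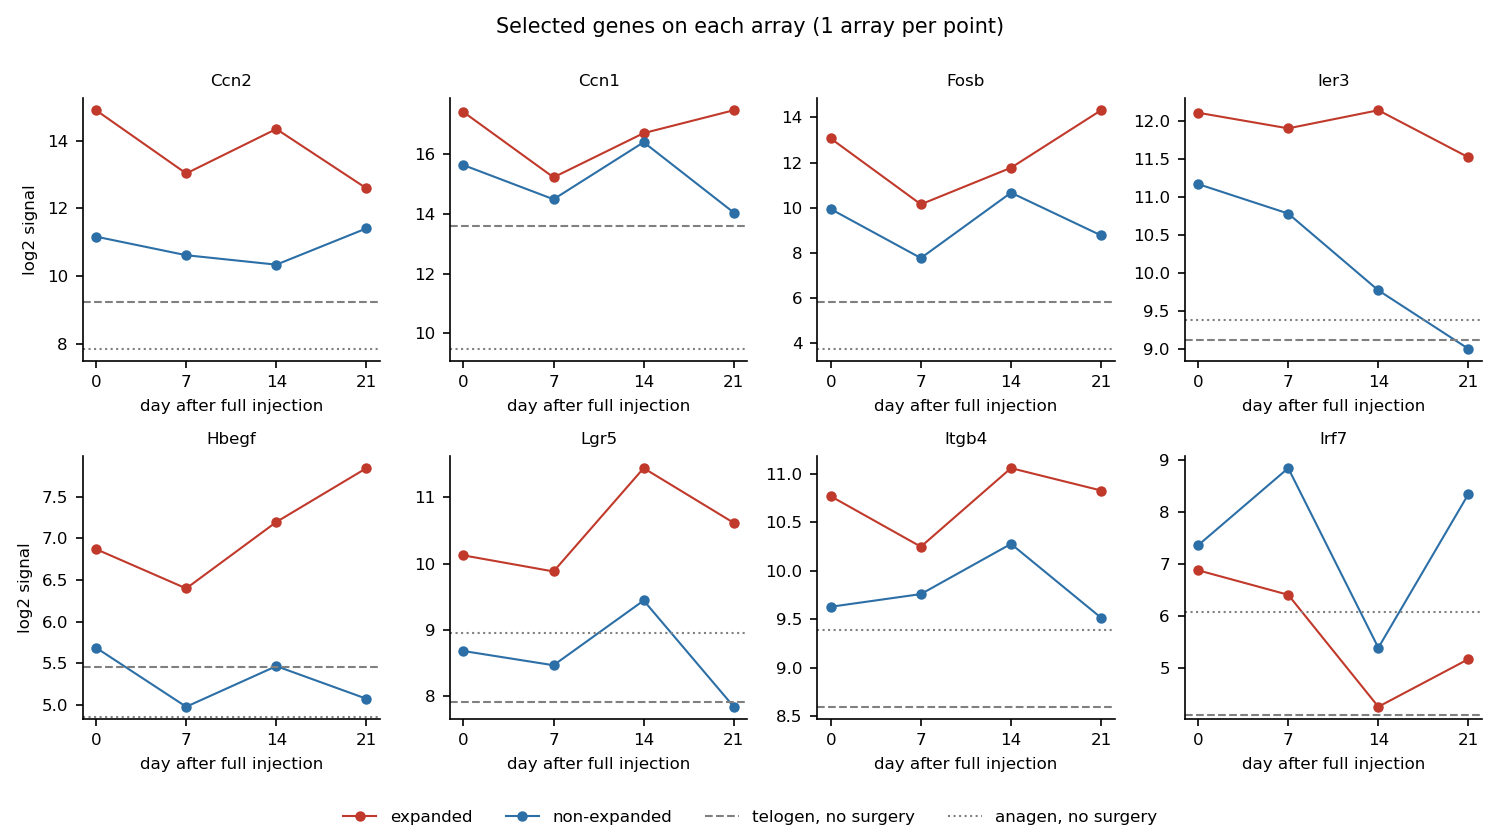
Log2 signal of 8 named genes (y axis) against the day after full injection, 1 array per point, with the telogen and anagen arrays as horizontal lines. Ccn2, Ccn1, Fosb and Lgr5 were higher in expanded skin at all 4 days.

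Keratinocyte genes were also higher. Basal epidermis genes rose, with 12 of 12 higher and a median of 0.64 (adjusted p = 1.15e-06, and adjusted p = 0.423 with an estimated correlation). Itgb4, Col17a1 and Itga3, which anchor basal cells to the basement membrane, differed by 0.93 ± 0.24, 0.83 ± 0.26 and 0.65 ± 0.23, Sfn, an adaptor protein of keratinocytes, by 1.90 ± 0.54 and the basal keratin Krt14 by 1.15 ± 0.41. Genes of epidermal differentiation rose, with 21 of 24 higher and a median of 0.65 (adjusted p = 0.000382, and adjusted p = 0.685 with an estimated correlation). Examples were Cdsn, of the cell junctions of the horny layer, at 0.99 ± 0.21 and Krt1 at 1.31 ± 0.49, while Krt10 differed by 0.24 ± 0.21. Genes of stress and wound epidermis rose, with 17 of 18 higher and a median of 1.23 (adjusted p = 0.000168, and adjusted p = 0.685 with an estimated correlation), and 3 passed over the list alone. The growth factor genes Hbegf and Ereg differed by 1.78 ± 0.31 and 1.26 ± 0.30, and the wound keratins Krt17 and Krt16 by 1.91 ± 0.51 and 4.29 ± 1.80. In non-expanded skin Hbegf averaged 5.30, under the background median of 5.46. Without day 7, epidermal differentiation (adjusted p = 0.161, median 0.31) and stress and wound epidermis (adjusted p = 0.462, median 0.27) were no longer called. At day 0 epidermal differentiation was lower in expanded skin, with 6 of 24 higher and a median of -0.63, below all 10000 random lists, against medians of 1.62, 0.84 and 0.64 at days 7, 14 and 21. Skeletal muscle genes moved the other way on the days after day 0, when the medians of stress and wound epidermis were 5.26, 2.40 and 0.99 at days 7, 14 and 21, against -2.65 at day 0. With the skeletal muscle covariate, epidermal differentiation was not called and turned (11 of 24 higher, median -0.06, adjusted p = 0.165), and stress and wound epidermis was called lower (median -2.28, adjusted p = 1.7e-09). With the hair mean as a covariate, neither epidermal differentiation nor stress and wound epidermis was called (adjusted p = 0.106 for both). Aqp3, a water and glycerol channel of the epidermis, differed by 3.22 ± 0.62 and the chemokine gene Cxcl14 by 2.88 ± 0.35.

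Among stem cell markers, Lgr6 (chromosome 1, 134983300 to 135105374) averaged 5.85 ± 0.49 in expanded and 6.49 ± 0.61 in non-expanded skin, close to the background median of 5.46. It differed by -0.64 ± 0.32 (limma adjusted p = 0.626), was higher in expanded skin on 1 of 4 days and did not pass. Lgr5, a marker of hair follicle stem cells (chromosome 10, 115450314 to 115587780), averaged 10.52 ± 0.69 against 8.61 ± 0.66 and differed by 1.91 ± 0.30 (adjusted p = 0.268), higher at all 4 days. It passed when adjusted over the list of epidermal and follicle stem cell markers alone, as 1 of its 17 genes, while the list as a whole was not called (6 of 17 higher, median -0.06, mean 0.02, adjusted p = 0.73). Cell cycle genes were higher in 23 of 33 cases with a median of 0.18 and were not called (adjusted p = 0.0878), and Mki67, made in dividing cells, differed by 0.39 ± 0.33. The days differed: cell cycle medians were -0.85, 0.73, 0.305 and 0.18 at days 0, 7, 14 and 21. Those of the stem cell markers were 0.07, 0.165, -1.01 and 0.71. Wnt pathway genes rose, with 8 of 9 higher and a median of 0.50 (adjusted p = 0.00842, and adjusted p = 0.58 with an estimated correlation), led by the Wnt antagonist gene Nkd2 at 0.79 ± 0.22 and by Wnt10a at 0.68 ± 0.22. BMP pathway genes rose, with 9 of 11 higher and a median of 0.27 (adjusted p = 0.0482, and adjusted p = 0.685 with an estimated correlation), and the BMP target Id1 differed by 1.23 ± 0.35. The Wnt pathway call ended without day 7 (adjusted p = 0.133) or day 21 (adjusted p = 0.0513), and the BMP pathway call without day 0, 7 or 21 (adjusted p = 0.131, 0.118 and 0.276). The Wnt pathway call also ended with the skeletal muscle, hair or immediate early covariate (adjusted p = 0.405, 0.139 and 0.193), and the BMP pathway call with the hair or immediate early covariate (adjusted p = 0.215 and 0.689).

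Fibrillar extracellular matrix genes, measured in whole skin, rose, with 16 of 21 higher and a median of 0.39 (adjusted p = 0.00221, and adjusted p = 0.707 with an estimated correlation), and 4 passed over the list alone. Tnc, Thbs2, Postn and Fmod, matrix proteins of loaded or healing tissue, differed by 2.78 ± 0.62, 1.66 ± 0.42, 1.06 ± 0.27 and 2.17 ± 0.56, while the main collagen genes Col1a1 and Col3a1 differed by -0.14 ± 0.51 and 0.19 ± 0.38. At day 7 the fibrillar extracellular matrix was lower in expanded skin, with 4 of 21 higher and a median of -0.85, below all 10000 random lists, against medians of 1.31, 0.75 and 0.95 at days 0, 14 and 21. The non-expanded array of day 7 stood apart, with a list mean of 14.50 (other days 12.74 to 13.01). On the expanded array of day 7 the mean was 13.74 (other days 13.77 to 14.22). The fibrillar extracellular matrix was not called without day 0 (adjusted p = 0.131, 10 of 21 higher) or with the immediate early covariate (adjusted p = 0.583, 9 of 21 higher). Matrix remodelling enzymes were not called (17 of 24 higher, adjusted p = 0.0673), though 4 passed over the list alone, and the collagen cross-linking enzyme gene Lox differed by 1.65 ± 0.30. The growth factor gene Igf2 and the binding protein gene Igfbp2 differed by 2.81 ± 0.75 and 3.17 ± 0.48.

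Interferon response genes fell in expanded skin: 9 of 11 were lower, with a median of -1.05 (adjusted p = 1.47e-05, and adjusted p = 0.566 with an estimated correlation), and 5 passed over the list alone. The antiviral factors Irf7, Oasl2, Ifit3 and Bst2 differed by -1.81 ± 0.46, -1.60 ± 0.38, -1.46 ± 0.38 and -1.32 ± 0.35, with Irf7 near background in expanded skin (mean 5.68). With the immediate early covariate, this interferon response call ended (adjusted p = 0.11). Retnla, made by alternatively activated macrophages, and Retnlg, of neutrophils, differed by -4.73 ± 1.04 and -2.71 ± 0.69, but the macrophage list (adjusted p = 0.238) and the neutrophil list (adjusted p = 0.0505) were not called. The major urinary protein genes Mup2, Mup9, Mup22 and Mup19, near-identical copies whose probe sets cannot be taken as separate measurements, differed by -4.42 ± 0.98, -4.38 ± 0.98, -4.36 ± 0.94 and -4.33 ± 0.92. Mast cell genes rose, with 7 of 8 higher and a median of 0.46 (adjusted p = 0.0473, and adjusted p = 0.58 with an estimated correlation), among them the stem cell factor receptor gene Kit at 1.15 ± 0.45. Adipocyte genes fell, with 14 of 17 lower and a median of -0.32 (adjusted p = 0.0322, and adjusted p = 0.685 with an estimated correlation). The mast cell call ended without day 7 (adjusted p = 0.248) or day 14 (adjusted p = 0.198), and the adipocyte call without day 14 (adjusted p = 0.71, 9 of 17 higher). With the skeletal muscle covariate, neither the mast cell nor the adipocyte list was called (adjusted p = 0.794 and 0.979), and with the hair covariate the mast cell list was not (adjusted p = 0.142).

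Hair genes were high on 1 expanded array, that of day 7. Genes of the hair shaft and inner root sheath rose, with 18 of 18 higher and a median of 1.23 (adjusted p = 0.00272, and adjusted p = 0.738 with an estimated correlation). Of the 150 anagen-high genes, 145 were higher, with a median of 1.08 (adjusted p = 3.29e-11, and adjusted p = 0.685 with an estimated correlation). The anagen-high genes hold all 18 hair shaft and inner root sheath genes and 4 of the 7 melanocyte genes, so the hair and anagen-high calls are not separate. Telogen-high genes fell, with 126 of 150 lower and a median of -0.87 (adjusted p = 4.52e-21, and adjusted p = 0.566 with an estimated correlation). The telogen-high genes, ranked on the telogen and anagen arrays, hold 11 of the 22 skeletal muscle genes, which fell as a group too. With the skeletal muscle covariate the telogen-high genes were still called, with a median of -0.50 (adjusted p = 9.53e-06). The hair shaft and inner root sheath (median -0.29, adjusted p = 0.457) and the anagen-high genes (median -0.39, adjusted p = 0.0717) then lay on the lower side and were not called. Without day 7, the hair shaft and inner root sheath (5 of 18 higher, median -0.24, adjusted p = 0.111) and the anagen-high genes (54 of 150 higher, median -0.23, adjusted p = 0.102) lay on the lower side and were not called. Melanocyte genes were not called (4 of 7 higher, median 0.08, mean -0.06, adjusted p = 0.548). On the same expanded array of day 7, the mean of stress and wound epidermis genes was 12.30, above the other 9 arrays.

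**Figure D3:**
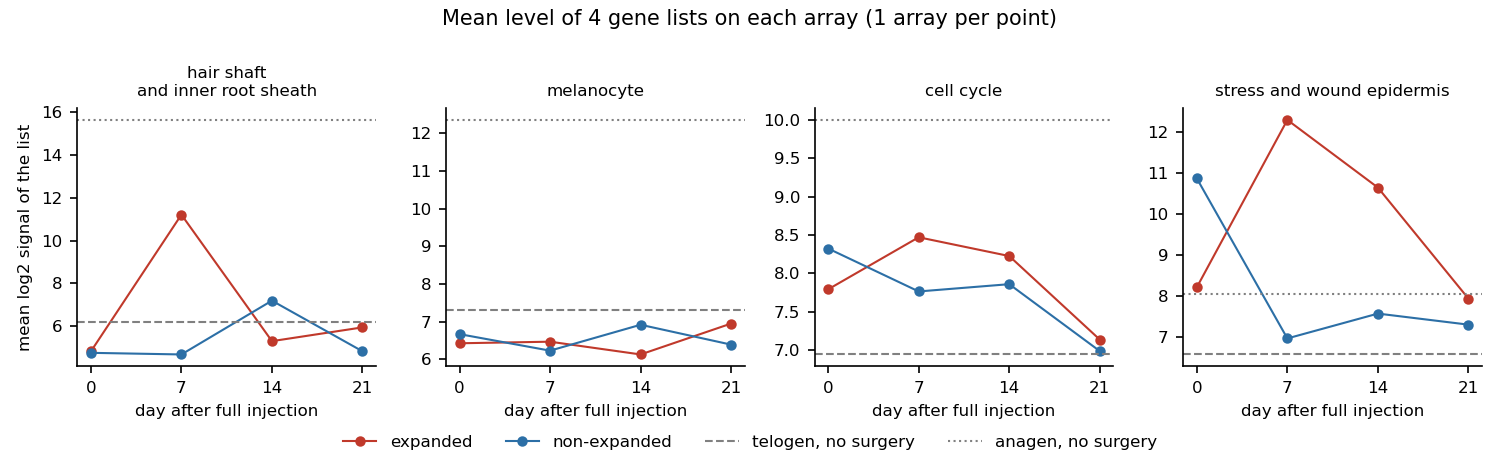
Mean log2 signal (y axis) of the hair shaft and inner root sheath, melanocyte, cell cycle, and stress and wound epidermis lists against the day after full injection, 1 array per point, with the telogen and anagen arrays as horizontal lines. On the expanded array of day 7 the hair mean was 11.22, against 15.64 in anagen and 6.18 in telogen skin.

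No gene passed an adjusted p of 0.05 in limma for the expansion effect (0 of 13653, lowest adjusted p = 0.221), while 1202 had an unadjusted p under 0.05, 659 of them higher, against 683 by chance. Camera with the preset correlation called 17 of 36 lists, 13 higher and 4 lower, and 0 with an estimated correlation (lowest adjusted p = 0.423). Some other splits of the 8 expander arrays gave as many genes at unadjusted p under 0.05 (up to 1696) or as many lists (up to 22). Chance was therefore not excluded for these counts. Without the block by day, 2 genes passed, Myh3 and Cxcl14 (both adjusted p = 0.0325), and without day 0 Myh3 alone (adjusted p = 0.00356). Without day 14 or day 21 the count at unadjusted p under 0.05 was 646 or 754, and with the skeletal muscle, hair or immediate early mean as a covariate it was 701, 1956 or 496. With the skeletal muscle covariate, 8 of the 17 lists were called in the same direction.

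**Figure D4:**
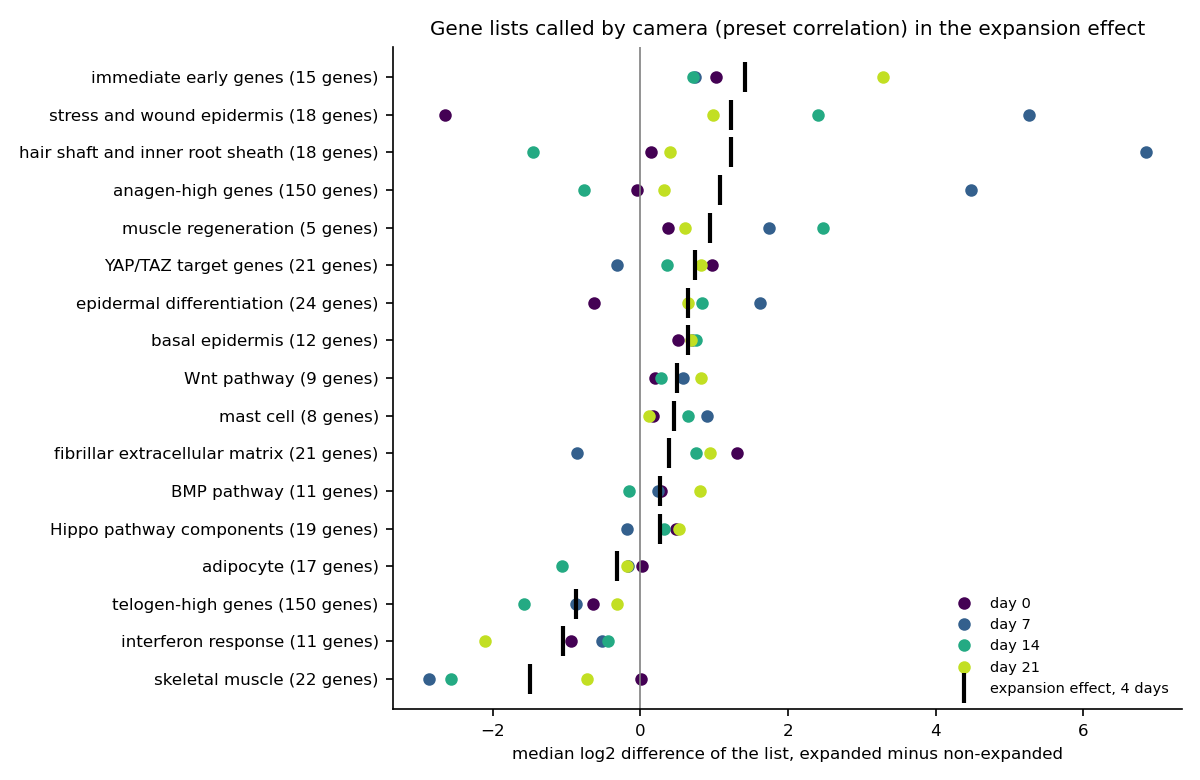
Median log2 difference of expanded minus non-expanded skin (x axis) for the 17 lists called by camera with the preset correlation, with points for single days and a bar for the effect over the 4 days. The bars run from -1.50 for skeletal muscle to 1.42 for immediate early genes, and the hair shaft and inner root sheath point of day 7 lies at 6.85.

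On single days the arms were compared with no replicates and no test. At day 0, 1295 genes were at least 2-fold higher and 844 at least 2-fold lower in expanded skin. The fibrillar extracellular matrix had a median of 1.31 and blood endothelium of 1.00, both above all 10000 random lists of matched level and both below all of them at day 7, while stress and wound epidermis stood at -2.65 and the sebaceous gland at -1.02, both below all of them. At day 7 the counts were 1153 and 1287, and the hair shaft and inner root sheath had a median of 6.85, stress and wound epidermis of 5.26, epidermal differentiation of 1.62, skeletal muscle of -2.86 and blood endothelium of -1.23. At day 14 they were 1560 and 1208, with muscle regeneration at 2.47, stress and wound epidermis at 2.40, macrophage genes at 1.20, skeletal muscle at -2.57 and the hair list at -1.46. At day 21 they were 914 and 837, with immediate early genes at 3.29, sebaceous gland genes at 0.98, interferon response genes at -2.10 and macrophage genes at -1.78. The same sign at all 4 days was shown by 1254 genes higher and 1106 genes lower in expanded skin, 17.3% of those tested against 12.5% by chance.

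The trends over the days ask how each arm changed after full injection and whether the arms changed differently. Cytokines and chemokines fell in expanded skin (15 of 17 lower, median change over 21 days -1.68, adjusted p = 1.5e-08, and adjusted p = 0.339 with an estimated correlation) and in non-expanded skin (15 of 17 lower, median -1.51, adjusted p = 4.38e-10, and adjusted p = 0.252 with an estimated correlation). Matrix remodelling enzymes fell in both arms, with medians of -0.78 (adjusted p = 5.02e-05, and adjusted p = 0.719 with an estimated correlation) and -0.69 (adjusted p = 0.00189, and adjusted p = 0.737 with an estimated correlation). Mmp12, a macrophage elastase gene, changed by -4.80 and -5.88 and the monocyte attractant gene Ccl2 by -1.81 and -5.42 over 21 days, and neither passed. Cell cycle genes fell in expanded skin (32 of 33 lower, median -0.71, adjusted p = 3.87e-06, and adjusted p = 0.719 with an estimated correlation) and in non-expanded skin (31 of 33 lower, median -1.24, adjusted p = 1.75e-11, and adjusted p = 0.737 with an estimated correlation). Without day 21, cell cycle genes were instead called higher over time in expanded skin (median 0.83, adjusted p = 0.000528), and without day 7 the matrix remodelling enzymes were not called in non-expanded skin (adjusted p = 0.294).

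Macrophage genes fell in expanded skin, with 17 of 17 lower and a median change of -1.61 (adjusted p = 7.71e-09, and adjusted p = 0.719 with an estimated correlation). Antigen-presenting cell genes fell there as well, with 6 of 7 lower and a median of -0.77 (adjusted p = 0.00852, and adjusted p = 0.719 with an estimated correlation). In non-expanded skin neither the macrophage nor the antigen-presenting cell list was called (adjusted p = 0.164 and 0.166). In non-expanded skin, stress and wound epidermis genes fell (17 of 18 lower, median -2.07, adjusted p = 0.000139, and adjusted p = 0.737 with an estimated correlation), though without day 0 they did not (median 0.09, adjusted p = 0.423). Adipocyte genes rose there (13 of 17 higher, median 0.74, adjusted p = 0.00232, and adjusted p = 0.737 with an estimated correlation), as did skeletal muscle genes (18 of 22 higher, median 0.93, adjusted p = 0.0152, and adjusted p = 0.856 with an estimated correlation). The adipocyte call ended without day 7 (adjusted p = 0.0541), the skeletal muscle call without day 21 (adjusted p = 0.0909) and the antigen-presenting cell call without day 14 (adjusted p = 0.054). The slow-muscle troponin genes Tnni1, Tnnc1 and Tnnt1 changed by 5.08, 4.70 and 4.60 over 21 days in expanded skin and did not pass. In non-expanded skin Tnnc1 and Tnnt1 changed by -1.52 and -0.72 and did not pass, and Tnni1 lay under the background median of 5.46 at days 7, 14 and 21 (4.91, 4.31 and 4.71), so no change is given for it there. Among genes of the non-expanded arm that did not pass, Il6 changed by -6.23, Ankrd1 by -8.66, Cxcl1 by -3.46 and Thbs1 by -2.46, while Mstn changed by 3.69. At days 14 and 21, Il6 (4.69 and 4.75) and Cxcl1 (5.27 and 5.39) lay under the background median, which limits their changes.

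The difference in time trend was tested directly. Immediate early genes had higher slopes in expanded skin (15 of 15 higher, median 1.80 over 21 days, adjusted p = 2.72e-06, and adjusted p = 0.817 with an estimated correlation), with the heat shock gene Hspa1a at 2.55 and Ier3 at 1.80. Sebaceous gland genes had higher slopes in expanded skin as well (13 of 13 higher, median 1.34, adjusted p = 3.11e-05, and adjusted p = 0.817 with an estimated correlation), with the lipid enzyme genes Fa2h, Far2 and Acsbg1 at 1.98, 2.03 and 1.79. Antigen-presenting cell genes had lower slopes in expanded skin (6 of 7 lower, median -1.59, adjusted p = 0.00094, and adjusted p = 0.741 with an estimated correlation), with the MHC class II genes H2-Ab1 and H2-Eb1 at -2.82 and -2.32. The calls of immediate early genes (adjusted p = 0.996), sebaceous gland genes (adjusted p = 0.442) and antigen-presenting cell genes (adjusted p = 0.0674) all ended without day 21, and the sebaceous gland call also without day 0 (adjusted p = 0.0849). Of single genes, Krt2, a keratin of the upper epidermis, differed in its change by 7.68 and Tnnc1 by 6.22.

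No gene passed in limma within expanded skin (0, with 339 at unadjusted p under 0.05), within non-expanded skin (0, with 495) or for the difference (0, with 166), and chance gives 683. The lowest adjusted p was 0.847, 0.437 and 0.999. Camera called 13, 13 and 12 of 36 lists, and 0 in each with an estimated correlation. Without day 0, 20 lists were called for the difference, but only 4 of the 12 were called in the same direction. Without day 0 the count at unadjusted p under 0.05 was 890 in expanded skin, 314 in non-expanded skin and 386 for the difference. Without day 7 it was 1092 in non-expanded skin and 506 for the difference, without day 14 it was 299 for the difference, and without day 21 it was 119 in expanded and 259 in non-expanded skin.

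The implantation effect asks how skin over an unfilled expander differed from skin without surgery. Macrophage genes rose, with 15 of 17 higher and a median of 3.31 (adjusted p = 6.21e-10, and adjusted p = 0.282 with an estimated correlation). Over the list alone 11 passed, among them Cd14 at 4.18 ± 0.62 and Lyz2, the macrophage lysozyme gene, at 4.49 ± 0.75 (SE, n = 4 and 2 arrays). Cytokines and chemokines rose, with 17 of 17 higher and a median of 2.96 (adjusted p = 1.09e-10, and adjusted p = 0.282 with an estimated correlation), and 11 passed over the list alone. Csf1, a macrophage growth factor gene, and Ccl8, Ccl3 and Ccl12 differed by 2.58 ± 0.47, 4.83 ± 0.91, 4.10 ± 0.83 and 3.66 ± 0.69. Matrix remodelling enzymes rose, with 23 of 24 higher and a median of 1.87 (adjusted p = 3.75e-11, and adjusted p = 0.282 with an estimated correlation), and 12 passed over the list alone. The collagen cross-linking genes Lox, Loxl1 and Loxl3 differed by 2.86 ± 0.43, 3.72 ± 0.68 and 2.98 ± 0.59, and the inhibitor gene Timp1 and the elastase gene Mmp12 by 6.76 ± 1.53 and 6.60 ± 1.62. Fibrillar extracellular matrix genes rose, with 20 of 21 higher and a median of 1.42 (adjusted p = 6.1e-07, and adjusted p = 0.311 with an estimated correlation), with Fn1, the fibronectin gene, at 3.70 ± 0.74. Further named genes that did not pass were Ccn3 at 6.40 ± 0.95, Clec4d, of neutrophils, at 6.19 ± 1.37, the complement gene Cfb at 5.66 ± 0.95 and the phagocyte oxidase genes Cybb and Ncf1 at 5.03 ± 0.98 and 4.95 ± 0.99. On both no-surgery arrays, Timp1, Clec4d and Ccl3 lay under the background median of 5.46, so the sizes of their differences are limited by background.

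Neutrophil (median 1.80, adjusted p = 0.000536), interferon response (1.41, adjusted p = 0.00022), blood endothelium (0.93, adjusted p = 8.98e-05), lymphatic endothelium (1.06, adjusted p = 0.00246), antigen-presenting cell (1.56, adjusted p = 0.00517), mast cell (1.02, adjusted p = 0.0118) and immediate early genes (1.36, adjusted p = 0.00022) also rose. With an estimated correlation, their adjusted p was 0.282, 0.311, 0.332, 0.282, 0.332, 0.282 and 0.341 in the same order. Hedgehog pathway genes fell, with 6 of 6 lower and a median of -1.24 (adjusted p = 9.93e-05, and adjusted p = 0.282 with an estimated correlation), and the receptor gene Ptch1 differed by -3.26 ± 0.64. Epidermal and follicle stem cell markers fell, with 12 of 17 lower and a median of -0.88 (adjusted p = 0.00022, and adjusted p = 0.282 with an estimated correlation). Over the list alone 7 passed, among them Gli1 at -2.55 ± 0.40 and the R-spondin receptor gene Lgr4 at -2.21 ± 0.37. BMP pathway genes (10 of 11 lower, median -1.02, adjusted p = 0.000149, and adjusted p = 0.296 with an estimated correlation) and Wnt pathway genes (9 of 9 lower, median -0.91, adjusted p = 0.000145, and adjusted p = 0.297 with an estimated correlation) fell as well. Hair and pigment genes moved with them: the hair shaft and inner root sheath fell, with 18 of 18 lower and a median of -6.07 (adjusted p = 1.37e-08, and adjusted p = 0.332 with an estimated correlation). Melanocyte genes fell too, with 7 of 7 lower and a median of -3.70 (adjusted p = 8.03e-06, and adjusted p = 0.296 with an estimated correlation). Krtap19-1, a hair shaft gene, and Tyrp1, an enzyme of pigment synthesis, differed by -9.21 ± 2.48 and -4.47 ± 1.36.

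Of the 2 no-surgery arrays, 1 was anagen skin, in which hair follicles are growing. Against the telogen array alone, the hair shaft and inner root sheath (median -0.75, adjusted p = 0.305), Wnt pathway (adjusted p = 0.175), Hedgehog pathway (adjusted p = 0.0613), antigen-presenting cell (adjusted p = 0.926), lymphatic endothelium (adjusted p = 0.312) and mast cell lists (adjusted p = 0.175) were not called. Against the telogen array alone, melanocyte genes were lower by less (7 of 7 lower, median -0.77, adjusted p = 0.0182) than against the anagen array alone (median -6.30, adjusted p = 2.42e-09), and Tyrp1 differed by -1.17 ± 0.65 and -7.78 ± 0.65. Cell cycle genes, which fell against both no-surgery arrays (31 of 33 lower, median -0.78, adjusted p = 0.00094, and adjusted p = 0.588 with an estimated correlation), rose against the telogen array (31 of 33 higher, median 0.82, adjusted p = 0.0015). Skeletal muscle genes, higher against both (20 of 22, median 1.23, adjusted p = 0.00848, and adjusted p = 0.588 with an estimated correlation), had a median of -0.72 against the telogen array (adjusted p = 0.148). Against the anagen array alone, the epidermal and follicle stem cell markers (adjusted p = 0.069), the mast cell list (adjusted p = 0.0502) and the immediate early genes (adjusted p = 0.18) were not called.

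**Figure D5:**
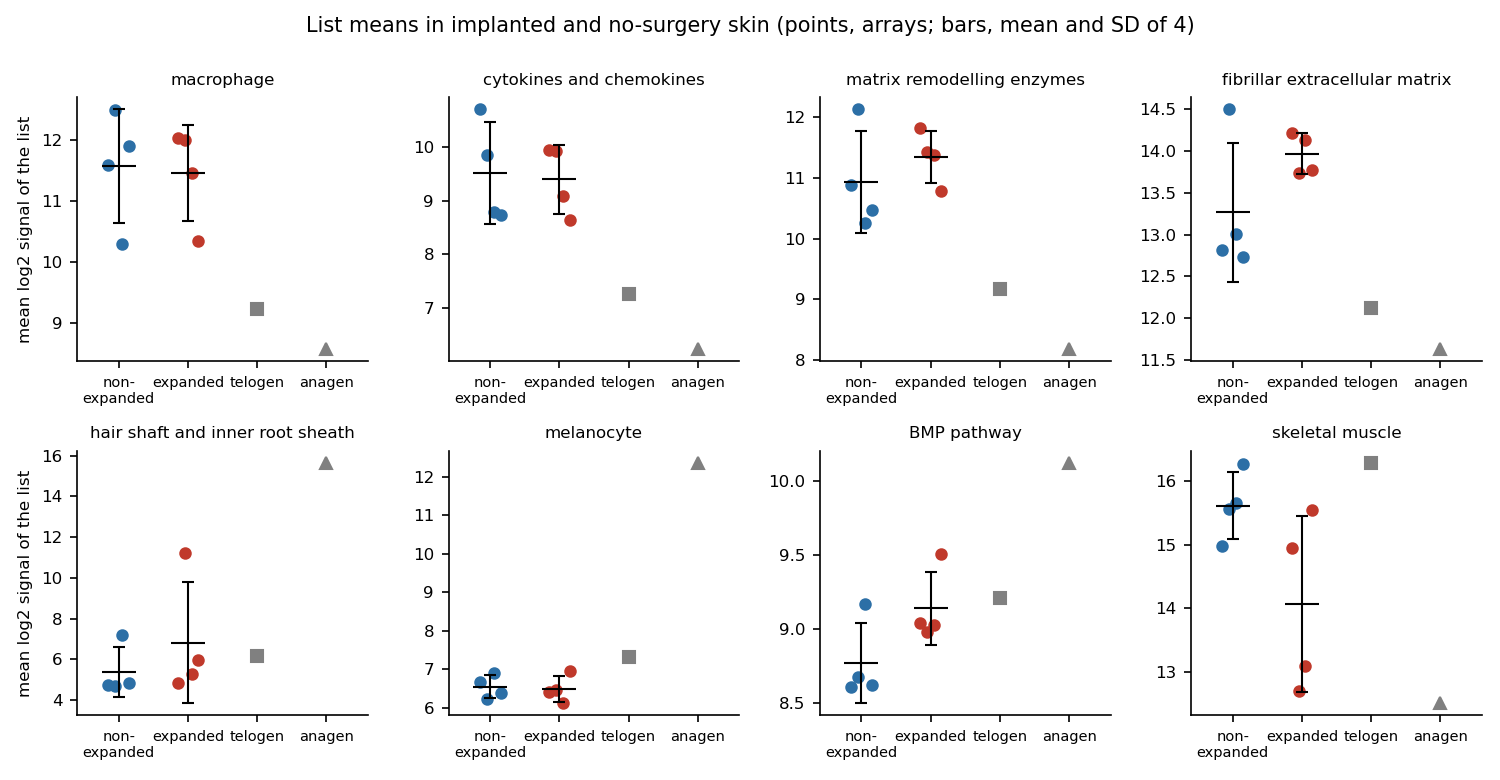
Mean log2 signal of 8 gene lists (y axis) in non-expanded, expanded, telogen and anagen skin, with points for arrays and bars for the mean and SD of 4 arrays. Macrophage genes averaged 11.57 ± 0.94 in non-expanded skin against 9.22 in telogen and 8.56 in anagen skin.

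No gene passed in limma for the implantation effect (0 of 13653), while 2144 had an unadjusted p under 0.05, 1286 of them higher, and the lowest adjusted p was 0.0646. Camera called 22 of 34 lists, 14 higher and 8 lower, and 0 with an estimated correlation (lowest adjusted p = 0.282). Without the non-expanded array of day 14, 112 genes passed, 106 of them higher. With the anagen array alone on the no-surgery side, 2645 genes passed, 1152 of them higher. With telogen alone, 13 lists were called.

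Anagen and telogen skin, with 1 array each and no test, differed in hair growth. Of 13653 genes, 3212 were at least 2-fold higher in anagen and 2788 at least 2-fold lower. The hair keratin gene Krt33a stood 11.88 higher, Tchhl1 11.65 and Krtap3-1 11.58, and Ctse, a protease gene, 12.02. In telogen skin Krt33a, Krtap3-1 and Ctse lay under the background median (4.49, 4.09 and 3.78), which limits the size of these differences. Hair shaft and inner root sheath genes had a median difference of 10.10, melanocyte genes of 5.85 and cell cycle genes of 3.37, each above all 10000 random lists. Wnt and Hedgehog pathway genes had medians of 2.32 and 1.81, at percentiles 99.99 and 99.2. Skeletal muscle genes had a median of -3.63 and circadian clock genes of -2.16, each below all 10000 random lists. Antigen-presenting cell and sebaceous gland genes had medians of -2.28 and -2.04, each at percentile 0.03. The muscle genes Mb and Tnnc2 stood at -7.11 and -7.03, and Lgr6 and Lgr5 at -0.58 and 1.05.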

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

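The tests of the muscle, hair and YAP/TAZ patterns in this part, and the count of distinct tests among the splits, were chosen after the results were seen, and the counts over other splits of the arrays were planned before.

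Among 140 groups of 4 arrays (gene lists and named genes in each arm), 14 had 1 array far from the other 3, where chance gives 7, about 1 in 20. In expanded skin, the array of day 7 stood apart in the mean of YAP/TAZ target genes (10.46, others 10.99 to 11.09), circadian clock genes (9.50) and anagen-high genes (10.49). The expanded array of day 0 stood apart in adhesion and mechanosensing genes (others 11.46 to 11.55), that of day 14 in Igf2 (12.98), and that of day 21 in BMP pathway genes (9.51), Apobec2 (11.16) and Eno3 (12.98). In non-expanded skin, the array of day 0 stood apart in stress and wound epidermis genes (10.88) and Krt16 (12.96), and that of day 7 in fibrillar extracellular matrix genes (14.50). The non-expanded array of day 14 stood apart in hair shaft and inner root sheath genes (7.20), interferon response genes (6.98) and BMP pathway genes (9.17).

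For 12 lists, camera with the preset correlation found that the change over the days differed between the arms, and with an estimated correlation it found 0 (lowest adjusted p = 0.741). With the day as a block, 10 of the 12 stayed called, and the adipocyte and the smooth muscle and pericyte calls were lost. The median difference of the change over 21 days, expanded minus non-expanded, was 1.80 for immediate early genes, 1.34 for the sebaceous gland, 0.94 for epidermal differentiation, 1.49 for stress and wound epidermis and 0.87 for the cell cycle. It was -1.59 for antigen-presenting cells, -1.54 for macrophages, -0.69 for hypoxia and glycolysis, -0.60 for smooth muscle and pericytes, -0.46 for adhesion and mechanosensing and -1.19 for anagen-high genes. For adipocyte genes the median was -0.10, with 8 of 17 higher. Without day 0, epidermal differentiation (median -1.08, adjusted p = 0.00466), stress and wound epidermis (median -7.67, adjusted p = 1.13e-25) and the cell cycle (median -0.85, adjusted p = 0.000673) were called in the other direction. Smooth muscle and pericyte and adhesion and mechanosensing genes also turned without day 0, and macrophage genes without day 21, and were not called (adjusted p = 0.0556, 0.169 and 0.0713). Anagen-high genes turned without day 7 and, relative to all other genes, without day 21, and were not called (adjusted p = 0.0944 and 0.951). The hypoxia and glycolysis call ended without day 0 or 21 (adjusted p = 0.215 and 0.0674) and the adipocyte call without day 0, 7 or 14 (adjusted p = 0.658, 0.137 and 0.232). Without day 14, the calls of the cell cycle (adjusted p = 0.0609), stress and wound epidermis (0.101), smooth muscle and pericyte (0.232), adhesion and mechanosensing (0.0738) and anagen-high genes (0.724) ended too. Outside the comparisons, 5373 of the 9243 probe sets without a gene symbol had a mean level above the median of the background probe sets.

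In expanded skin, genes of developing muscle were higher and genes of adult muscle lower. A smaller piece of the muscle layer in the expanded samples would lower both, yet the muscle regeneration list had a mean difference of 2.16 and lay above the skeletal muscle mean by 0.93, 5.43, 5.79 and 2.69 at days 0, 7, 14 and 21, which argues against it for the rise. Myh3, at 7.24, raised this mean. The medians of the 5 genes were smaller, 0.38, 1.74, 2.47 and 0.60 on these days, with 4 of 5 higher on each. The list holds 9 genes, of which only these 5 passed the level filter. That filter used the expanded arrays too, so it favoured genes high in expanded skin. For the fall, 1 common loss would put about 1.1 of the 22 skeletal muscle genes beyond their own 95% interval from the list median of -1.50, but 5 lay beyond it, 4 above (Myh2, Myl1, Actn3 and Cacng1) and 1 below (Tnnc2), which argues against 1 common loss as the whole cause. Myl1 lies near the top of the scale, where differences could be compressed. A change within the muscle layer under expansion may account for both, as a hypothesis, and a smaller share of muscle stays open for the fall.

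On the expanded array of day 7, hair genes were high. If RNA of anagen skin had been mixed into that sample, the median hair offset from the anagen array (-4.75, a share of 3.71%) would set the level of melanocyte genes. These lay below the needed level by a median of observed minus needed of -1.87 (SD 0.985, 7 of 7 genes below). This argues against a mixture with RNA like that of the anagen array at this share. Hair offsets ran from -1.82 (Tchh) to -6.43 (Padi3), so the share is uncertain. RNA of anagen skin at another stage was not tested. The same test at the lower quartile of the hair offsets gave -1.66 (SD 0.908). Inner root sheath genes lay closer to the anagen array (median offset -3.23, 7 genes) than shaft keratins (-4.86, 7 genes). Their offsets overlapped, from -1.82 to -4.965 against -3.84 to -6.26. In anagen the inner root sheath genes read 16.21 to 18.98, high on the scale, where differences could be compressed. An earlier stage of hair growth in that sample may account for the pattern, and whether it came with expansion stays open, since it rests on 1 array.

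YAP/TAZ target genes were higher in expanded skin by a mean of 0.89 ± 0.26 (SE, 0.65 ± 0.30 without Ankrd1). With the mean of the immediate early genes as a covariate, to test a stress response during tissue handling, the difference was 0.50 ± 0.43. Without Ankrd1 it was 0.32 ± 0.54, both with 2 residual degrees of freedom. Immediate early genes were higher in expanded skin at days 0, 7, 14 and 21 (by 1.25, 0.65, 0.75 and 3.36). On these days the mean of the YAP/TAZ target genes differed by 1.12, 0.12, 1.02 and 1.29. Without Ankrd1 it differed by 1.17, -0.18, 0.68 and 0.93, so it was not higher at day 7. With 1 array per arm on each day, expansion and handling could not be told apart for the YAP/TAZ target genes.

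With the day as a block, 32 splits of the 8 expander arrays could be fitted. Splits that part both arrays of only 2 days come in pairs with the same fit, which leaves 20 distinct tests, too few for a share under 0.05. With the real split included, 7 of the 32 splits, or 5 of the 20 distinct tests, gave at least the real 1202 genes at unadjusted p under 0.05, and the highest other gave 1696. Among the 8 splits that part both arrays of every day, 3 gave as many, the real one included, and the highest other gave 1375. For the 17 called lists, 5 of the 32 splits gave as many, the real one included, all 5 of them among those 8, and the highest other gave 22. Regrouped arrays thus gave as many genes and as many lists as the real arms. Chance was therefore not excluded for either count of the expansion effect. For the difference in time trend, chance was not excluded: with the real split included, 35 of 35 splits (34 distinct tests) gave at least the 166 genes of the real arms. The highest other gave 1162, several times as many, and the cause was not tested. The sides of that split hold unequal days, so changes that are not straight lines over the days enter its count. Among the 8 splits that part both arrays of every day, all 8 gave at least 166, and the highest other gave 1057. Such counts thus also arose with equal days on both sides.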

How the results depend on the processing

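Chosen after the results were seen were the covariate fits, the list without Ankrd1, the list tests of the trend within each arm with all their repeats, and the list tests with the telogen or anagen array alone and with the block for the difference in time trend. The other alternatives were planned before.

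Of the results for single genes under the alternatives, 2923 kept their direction and their side of the threshold, 107 passed it in the same direction and 12 changed direction. For lists, direction is that of camera, against all other genes: 396 kept both, 161 kept only their direction and 27 changed it. The median lay on the other side of 0 for 9 of the 161 and for 26 of the 27. Quantile normalization, centring, the trended and robust prior and the mean of all probe sets changed no call of a gene, and quantile normalization ended no call of a list. With an estimated correlation, 0 lists were called in each of the 5 comparisons, and the cause was not tested beyond the fact that such a test draws its degrees of freedom from the few arrays. Without Ankrd1, YAP/TAZ target genes kept an adjusted p of 0.000132.

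The counts at unadjusted p under 0.05 moved with the filter for the non-expanded trend, from 495 to 807 with no filter and to 304 with the stricter filter, and for the difference in time trend, from 166 to 365 and 94. More or fewer genes were tested, which contributes by construction. Without the replicate block, the expansion effect had 2 called genes against 0, 1246 at unadjusted p under 0.05 and the same 17 lists. With the block, the difference in time trend had 146 genes at unadjusted p under 0.05 and 10 of its 12 lists. The calls of adipocyte genes (adjusted p = 0.0585) and smooth muscle and pericyte genes (adjusted p = 0.0536) were lost, and the block changed no other call. In lists placed by day, T and NK cell genes at day 14 moved from percentile 0.49 to 72.1 with no filter, and the cause was not tested.

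With the skeletal muscle list as a covariate, 701 genes had an unadjusted p under 0.05, with the hair list 1956 and with the immediate early list 496, against 1202. The skeletal muscle covariate turned the direction of hair shaft and inner root sheath (adjusted p = 0.457), anagen-high genes (0.0717), epidermal differentiation (0.165), stress and wound epidermis (1.7e-09, median -2.28) and mast cell genes (0.794). The immediate early covariate turned BMP pathway genes (adjusted p = 0.689). The fits with a covariate leave 2 residual degrees of freedom, and the cause was not tested.

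Against the telogen array alone, the implantation effect turned for Aurka (0.0019), Ect2 (0.33), Hmmr (0.73), Cd209a (-0.092), Ccl21a (-0.21) and Wnt5a (0.28). It also turned for cell cycle (adjusted p = 0.0015, median 0.82) and skeletal muscle genes (adjusted p = 0.148), and 13 lists were called against 22. Against the anagen array alone, 2645 genes were called against 0, and 4707 against 2144 had an unadjusted p under 0.05. The no-surgery arm holds fewer samples of another hair stage in these fits, where the lone array is assumed to vary like the other groups, and beyond that the cause was not tested.

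Without each day in turn, where fewer samples contribute by construction, the genes of the expansion effect called numbered 0 to 1, and 646 to 1646 had an unadjusted p under 0.05. The latter count ran from 119 to 890 for the expanded trend (12 to 21 lists), from 259 to 1092 for the non-expanded trend (8 to 13 lists) and from 198 to 506 for the difference in time trend (6 to 20 lists). For the implantation effect, 0 to 112 genes were called without each non-expanded array. Some results turned without 1 day. For the expansion effect, these were Yap1 (-0.45 to 0.25), Col1a1 (-0.52 to 0.51), Col3a1 (-0.086 to 0.66), hair shaft and inner root sheath (adjusted p from 2.39e-08 to 0.111) and anagen-high genes (2.37e-22 to 0.102). In the expanded trend, they were cell cycle (adjusted p from 1.33e-15 to 0.0031), adhesion and mechanosensing (0.00256 to 0.928), immediate early genes (6.88e-07 to 0.803), anagen-high genes (1.55e-53 to 0.0787) and telogen-high genes (2.21e-14 to 0.0283). In the non-expanded trend, they were stress and wound epidermis (adjusted p from 3.47e-09 to 0.423), sebaceous gland (0.000436 to 0.952) and blood endothelium (0.00115 to 0.326). In the difference in time trend, they were Itgax (-4.07 to 0.64), cell cycle (adjusted p from 4.56e-06 to 0.0609), epidermal differentiation (1.49e-06 to 0.00466), stress and wound epidermis (1.13e-25 to 0.101), smooth muscle and pericyte (8.14e-06 to 0.232), adhesion and mechanosensing (0.0029 to 0.169), macrophage (3.5e-08 to 0.0713) and anagen-high genes (4.57e-44 to 0.951). Beyond the smaller number of samples, the cause was not tested.

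Of the genes tested, 1486 of 13653 (10.9%) had a mean level under the background median of 5.46, and differences of these genes are limited by background.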

Other observations

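The values in this part were chosen for description after they were seen, and none was tested beyond the comparisons above.

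The lists of vessel, nerve and metabolic genes were not called for the difference between the arms over the 4 days. Blood endothelium genes had a median expansion difference of 0.01 (7 of 14 higher, limma camera adjusted p = 0.981), lymphatic endothelium genes of 0.28 (4 of 6 higher, adjusted p = 0.548) and Schwann cell and nerve genes of 0.07 (2 of 4 higher, mean -0.30, adjusted p = 0.335). Mbp, the myelin basic protein gene, differed by -1.49 ± 0.31 and passed when adjusted over its list alone. Smooth muscle and pericyte genes had a median of -0.13 (9 of 13 lower, adjusted p = 0.0607), with the contractile genes Myl9, Lmod1 and Actg2 at -0.91 ± 0.34, -0.92 ± 0.34 and -1.26 ± 0.51. Hypoxia and glycolysis genes had a median of -0.02 and a mean of 0.26 (6 of 13 higher, adjusted p = 0.26), and 2 passed over the list alone, led by the oxygen sensor gene Egln3 at 1.60 ± 0.33. The glucose transporter gene Slc2a1 differed by 1.12 ± 0.30.

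The growth factors and receptors list was not called (9 of 12 higher, median 0.21, adjusted p = 0.125). Among adhesion and mechanosensing genes (9 of 17 higher, adjusted p = 0.32), the stretch-gated channel gene Piezo2, under the background median of 5.46 in non-expanded skin (mean 4.92), differed by 1.63 ± 0.34 and the actin cross-linkers Actn4 and Actn1 by 1.18 ± 0.31 and 0.62 ± 0.25. Circadian clock genes had a median of -0.23 (5 of 11 higher, adjusted p = 0.633), with the clock output gene Dbp at -0.96 ± 0.37. T and NK cell genes had a median of 0.05 (7 of 9 higher, adjusted p = 0.753). Sebaceous gland genes had a median of -0.34 (10 of 13 lower, adjusted p = 0.0848), with the duct marker Krt79 at 1.15 ± 0.30 and the lipid genes Awat2 and Scd3 at -1.17 ± 0.40 and -1.35 ± 0.49.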
